A study of Mus musculus with 140 samples.

How the data were processed

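Single-cell RNA sequencing by Smart-seq3xpress, a plate-based method that reads 1 sorted cell per well, was analysed for 140 samples of mouse embryos (strain C57BL/6XC3H). Per the labels' protocols, tissue was dissociated with trypsin, stained with anti-EpCAM-APC and DAPI, and sorted on a FACSAria. EpCAM is an epithelial surface protein, and DAPI excludes dead cells. A sample is 1 line at 1 somite stage (SS) and 1 replicate number. The 9 lines Hhex, Mnx1, Mnx1GFP, Nepn, Nkx2_3, Pax9, Pdx1, Sox2 and Wnt5b each gave 2 samples at 9, 12, 15, 18, 21, 24 and 27 SS. In 8 of them the named gene drives CreER, a tamoxifen-dependent recombinase that marks cells and their descendants for good. Their labels give tamoxifen at E8.0. Pdx1 is a GFP reporter of current expression. Ngn3Cre (Ngn3-Cre with the Ai6 reporter) gave 1 sample at each of 4 stages. Ngn3GFP HM (both copies GFP) and HZ (1 copy GFP) gave 1 sample at each of 5 stages.

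Per the submitters' processing notes, the authors used FastQC 0.11.9, Trimmomatic 0.39 and HISAT2 2.1.0 on GRCm38/mm10. The counting tool, the annotation and any filter on cells are not given in the sources used here. The deposited table holds raw read counts per gene and cell, without normalization. For most samples the deposited values were first recorded under the heading other, because only some columns were read one by one when the unit was set. A test of every value of every column then found the same whole-number counts, with none below 0. The table has 26313 genes, of which 1166 had no read, and no mitochondrial gene. The list of mitochondrially encoded genes could therefore not be measured. A TPM table of the same cells was not analysed here. Gene positions came from an annotation of GRCm38, in which 25477 genes matched 1 position.

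All 25847 cells of the table were kept. They had a median of 563300 reads and 8120 detected genes. The reads of the cells of a sample were summed gene by gene, since cells of 1 sample are not independent replicates. The sums hold 10.5 to 367 M reads (M for mega). At that depth a gene at 1 read per M reads (1 CPM) has at least 10 reads in a sample. The labels do not say what the replicate numbers stand for. The p-values thus measure the spread between these samples, which may be technical in part.

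Genes were tested with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, after filterByExpr and TMM normalization. Benjamini-Hochberg adjusted p under 0.05 counted as a call. The 126 samples of the 9 lines were fitted with line as a factor and somite number as a slope, with a slope per line, and with line and stage as factors. From the last fit each line was set against the mean of the other 8, and Mnx1GFP against Mnx1. HM and HZ, and Ngn3Cre and HZ, were compared in fits of their own with stage as a factor. Slopes are log2 changes over 18 somites, from 9 to 27 SS. Errors of log2 fold changes (±) are standard errors, the size of the change over the root of F. Group means are log2 CPM with a prior count of 1, ± SD. No replicate block was used, because the labels do not say that replicate numbers pair samples. Over 252 pairs of groups of 1 stage, the correlation across genes of their replicate differences had a median of 0.022. It ranged from -0.691 to 0.733, with 79 pairs over 0.1 and 60 under -0.1. Replicate numbers thus had no common direction, but differences shared by some groups remain possible. All tests are two-sided.

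Gene lists were tested with camera (limma 3.58.1), a competitive test, with a preset correlation of 0.01 between genes and again with an estimated one. Adjustment ran over the lists of a comparison. The 34 measured lists, the comparisons, the tests and the rule for naming genes were chosen before the data were examined. The lists cover pharyngeal endoderm, thyroid and lung bud, esophagus and stomach, hepatic, pancreatic progenitor, endocrine, extrahepatic biliary and ventral pancreas, midgut and small intestine, and hindgut genes. They also cover anterior Hox, posterior Hox, definitive endoderm core, early embryonic, fetal maturation, hedgehog, Wnt feedback, BMP response, FGF response, Notch and retinoic acid genes. The rest are S phase, G2 and M phase, glycolysis, dissociation stress, p53 targets, extraembryonic endoderm, notochord and node, mesenchyme and mesoderm, cardiac, endothelium, blood, surface ectoderm, neural, and primordial germ cell genes. Lists share members, so they are not independent.

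Genes named are the 9 driver and reporter genes, those with the largest changes, and up to 4 members of a list with the smallest p. The largest changes were the 10 highest and 10 lowest of a comparison, or the 5 highest and 3 lowest of a line. They had to be called, have a mean of at least 5 log2 CPM and keep 1 sign in every stage or replicate number. For slope differences, the 10 smallest p were taken. Predicted genes without a proper symbol were left out.

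Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2: 100000 reads per cell after scaling, 2000 variable genes, 30 principal components, 20 neighbours and resolution 1, which gave 40 clusters. A cluster took a cell type's name when at least 3 of its markers were at least 1 log2 above the other cells, with a pseudocount of 5 CPM. Clusters stayed unnamed with over 66.7% of cells from 1 sample, with low depth, with 3 macrophage genes among the top 10 genes, or when the top 10 held more markers of another type in the marker list. By the last rule a cluster with 9 of 9 hindgut markers stayed unnamed, which made 16.2% of Wnt5b and 8.0% of Mnx1, so hindgut-like shares leave it out. By the 1-sample rule clusters 29 (mostly Mnx1GFP) and 34 (mostly Wnt5b), with 6 and 7 of 9 hindgut markers, are left out too. In all 29 clusters were named and 11, with 27.5% of the cells, were not. Cluster 33 took the endothelium name, but 5 of its top 10 genes are cardiac (Tnnt2, Actc1, Myl4, Tnni1 and Myl7), a type without markers in that list. Its name and share are not used, and its cells count as non-endodermal. Names end in -like because they rest on markers alone, and no doublet caller was run. Driver and reporter genes are themselves markers and list members, so part of a line's enrichment for its own type can be built in. Shares were compared by permuting line labels within stage (100000 draws, so 1e-05 is the smallest p possible), adjusted over 135 pairs. For HM against HZ an exact sign-flip test over stages was used. Shares of single samples have exact (Clopper-Pearson) 95% intervals. A count of 0 is given with the share that 3 cells would make. Intervals and limits cover counting error only.

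Each test was tested on simulated counts with 200 genes changed. For genes from 1 CPM, 2-fold changes were recovered in 92.1% for somite number, 93.8% for the Hhex line, 81.9% for the Mnx1 pair, 12.9% for HM against HZ and 4.9% for Ngn3Cre against HZ. For 4-fold changes the last pair gave 69.6% and 56%. The slope difference test, with a change in 1 line, recovered 37.1% and 66%. Over all 20824 genes that test called 151 unchanged genes, of which 9 lay above 1 CPM, so its calls near the floor are unreliable. The other 5 comparisons called 7 to 31 unchanged genes.

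Alternatives were the DESeq2 1.42.0 test, its size factors (RLE) in edgeR, no filter on low counts, a replicate block, and leaving out each replicate number, stage or line. Further ones were cells thinned to 100000 reads, cells with under 2000 genes left out, clustering resolutions of 0.5 and 2, 27 SS against 9 SS only, and all 140 samples in 1 fit. Added after the data were seen were a term for an axis of library differences, leaving out non-endodermal or neural-like clusters, hindgut-like cells only, leaving out samples with carried-over transcripts, and counts of genes from 1 CPM.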

Results

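The data describe how the mouse embryonic gut tube, the endoderm that forms the pharynx, thyroid, liver, pancreas and intestine, changed between 9 and 27 somites. They hold 140 samples with 25847 cells, each cell sequenced on its own. The 9 lines followed over the whole period gave 24816 cells, 60 to 480 cells and 16.7 to 367 M reads per sample (M for mega). Pdx1 had the fewest cells (1329) and the least reads, from 16.7 M per sample, and Sox2 the most cells (3569, 104 to 210 M). The other lines had 84.9 to 185 (Hhex), 122 to 367 (Mnx1), 31.6 to 159 (Mnx1GFP), 94.7 to 177 (Nepn), 76.3 to 177 (Nkx2_3), 46.5 to 147 (Pax9) and 96.8 to 161 M (Wnt5b). The 14 samples of the Neurog3 (Ngn3) lines held 1031 cells, 22 to 159 per sample, and 10.5 to 91.1 M reads. The 2 samples of a line and stage correlated at 0.844 to 0.99 across genes, which are not independent replicates.

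Among the 9 time-course lines, most driver and reporter genes were highest in the lines named after them. Hhex (ENSMUSG00000024986.12, chromosome 19, 37434810 to 37440731), a homeobox gene of the liver and thyroid buds, stood at 7.70 ± 0.47 log2 CPM in the Hhex line (SD, n = 14). Nkx2-3 (ENSMUSG00000044220.13, chromosome 19, 43612325 to 43615892), a pharyngeal homeobox gene, stood at 7.44 ± 0.64 in Nkx2_3. Pax9 (ENSMUSG00000001497.18, chromosome 12, 56691767 to 56712822), a gene of the pharyngeal pouches, stood at 7.72 ± 0.78 in Pax9. Pdx1 (ENSMUSG00000029644.7, chromosome 5, 147269959 to 147275848), a regulator of pancreas and duodenum, stood at 5.32 ± 0.89 in Pdx1. Nepn (ENSMUSG00000038624.13, chromosome 10, 52388972 to 52404625), which encodes a secreted proteoglycan of the gut, stood at 10.28 ± 0.59 in Nepn, below its 10.96 in Ngn3GFP HM and 10.48 in HZ. Mnx1 (ENSMUSG00000001566.9, chromosome 5, 29473034 to 29478470), a motor neuron and pancreas homeobox gene, stood at 5.28 ± 0.72 in Mnx1GFP and 4.24 ± 0.49 in Mnx1. Wnt5b and Sox2 were not highest in their own lines. Wnt5b (ENSMUSG00000030170.14, chromosome 6, 119432531 to 119544347), a posterior Wnt ligand, was at 6.51 in Mnx1GFP, 6.01 in Mnx1 and 5.70 in Wnt5b. Sox2 (ENSMUSG00000074637.7, chromosome 3, 34650405 to 34652461), a regulator of anterior gut and neural tissue, was at 7.11 in Pax9, 6.85 in Sox2 and 6.74 in Nkx2_3. All positions are on GRCm38.

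**Figure D1:**
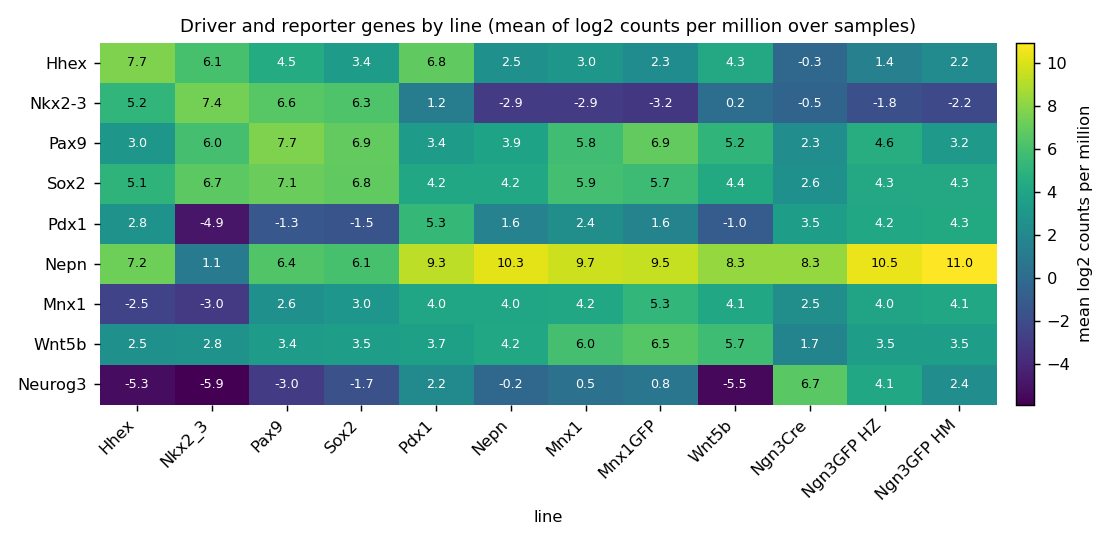
Mean log2 CPM of the driver and reporter genes (vertical) in each of the 12 lines (horizontal), n = 14 samples for the time-course lines, 4 for Ngn3Cre and 5 for each Ngn3GFP genotype. Hhex, Nkx2-3, Pax9 and Pdx1 are highest in the lines named after them, at 7.70, 7.44, 7.72 and 5.32.

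The first comparison asked which genes changed between 9 and 27 somites over the sorted samples of the 9 lines. The sums include cells of named non-endodermal clusters (2428 of the 25847 cells of all samples). A change of cell makeup with stage can therefore enter these slopes. Sema3c (ENSMUSG00000028780.13, chromosome 5, 17574281 to 17730268), a guidance ligand, rose 6.49-fold (log2 2.70 ± 0.15, adjusted p 1.38e-31), from 4.13 ± 1.01 at 9 SS to 6.82 ± 0.52 at 27 SS (n = 18 each). Spink1 (ENSMUSG00000024503.3, chromosome 18, 43728082 to 43737557), a protease inhibitor of early endoderm, was 20.2-fold lower (log2 -4.34 ± 0.25, adjusted p 2.4e-31). Podxl (ENSMUSG00000025608.9, chromosome 6, 31519488 to 31563981), which encodes an apical sialomucin, fell from 9.24 ± 0.50 to 7.32 ± 0.24. The paternally expressed Notch-like ligand gene Dlk1 rose by 1.96 ± 0.14 on the log2 scale, the nuclear receptor gene Nr2f2 by 1.87 ± 0.16, the guidance receptor gene Nrp2 by 1.52 ± 0.15 and the serpin gene Serpinf1 by 1.43 ± 0.13. The matrix gene Vtn (1.47 ± 0.17) and the metallothionein gene Mt1 (1.42 ± 0.19) rose too. The carbonic anhydrase genes Car4 and Car2 changed by -2.57 ± 0.17 and -2.23 ± 0.18, the imprinted gene Phlda2 by -2.60 ± 0.23, the basement membrane gene Nid2 by -1.92 ± 0.11 and the RNA-binding protein gene Lin28a, a brake on maturation, by -1.80 ± 0.17. Of 19705 genes tested, 4583 rose and 4201 fell, and 2330 of them changed more than 2-fold (1757 up, 573 down). With replicate 1 left out the count was 4793.

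Division genes fell with age. Of 22 S phase genes 21 fell and 0 rose (21 adjusted over the list alone), with a median log2 change of -0.41, and this list was the only 1 of the 13 called whose call held with an estimated correlation (adjusted p 0.0282). The helicase gene Mcm5 fell by 0.56 ± 0.05 and the replication genes Gins2 and Pcna by 0.68 ± 0.06 and 0.55 ± 0.06. Of 21 G2 and M phase genes 19 fell (19 adjusted over the list alone, adjusted p = 0.161 with an estimated correlation), among them the kinase genes Aurka (-0.59 ± 0.06) and Cdk1 (-0.49 ± 0.06). Hormone cell genes rose: 34 of 49 endocrine genes were higher and 2 lower (34 and 3 adjusted over the list alone, adjusted p = 0.161 with an estimated correlation). They include the prohormone-processing gene Cpe (1.58 ± 0.12) and the islet regulator genes Isl1 (1.38 ± 0.15) and Nkx2-2 (2.38 ± 0.31). Of 22 pancreatic progenitor genes 15 rose and 1 fell (17 and 1 adjusted over the list alone; 0.161). The hepatic list was called upward with 10 of 25 genes up and 6 down (11 and 7 adjusted over the list alone; 0.558), led by the liver regulator gene Cebpa (3.48 ± 0.28). In the surface ectoderm list 10 of 14 rose and 1 fell (12 and 1 adjusted over the list alone; 0.161), with the epidermal gene Trp63 up by 2.59 ± 0.23. In the fetal maturation list of mostly imprinted genes 7 of 12 rose and 1 fell (7 and 1 adjusted over the list alone; 0.161), with Plagl1 up by 2.31 ± 0.23 and the growth factor gene Igf2 by 0.86 ± 0.15.

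Of the remaining lists called, all but posterior Hox were called downward, and none of these calls held with an estimated correlation. In the definitive endoderm list 11 of 20 fell and 2 rose (11 and 4 adjusted over the list alone; adjusted p = 0.18 with an estimated correlation), with the endoderm regulator gene Sox17 at -2.62 ± 0.27 and the neuropeptide gene Trh at -2.27 ± 0.35. In the early embryonic list 7 of 18 fell and 2 rose (7 and 2 adjusted over the list alone; 0.148), with the DNA methyltransferase gene Dnmt3b at -1.18 ± 0.08 and L1td1 at -1.24 ± 0.14. In the Wnt feedback list 9 of 16 fell and 2 rose (9 and 2 adjusted over the list alone; 0.246), with the Wnt target gene Sp5 at -2.12 ± 0.23 and the inhibitor gene Dkk1 at -1.56 ± 0.22. In the BMP response list 5 of 14 fell (5 adjusted over the list alone; 0.264), with Id3 at -0.81 ± 0.07 and Id1 at -0.68 ± 0.08. In the extraembryonic endoderm list 15 of 20 fell and 1 rose (16 and 1 adjusted over the list alone; 0.341), with the lactate transporter gene Slc16a1 at -1.74 ± 0.12 and Rhox5 at -3.32 ± 0.36. In the posterior Hox list 11 of 22 rose and 2 fell (11 and 2 adjusted over the list alone; 0.634). Among the driver genes Pdx1 (2.49 ± 0.43), Neurog3 (3.94 ± 0.70), Hhex (0.81 ± 0.28) and Sox2 (0.56 ± 0.13) rose, while Nkx2-3 (-1.79 ± 0.40) and Wnt5b (-1.14 ± 0.16) fell.

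**Figure D2:**
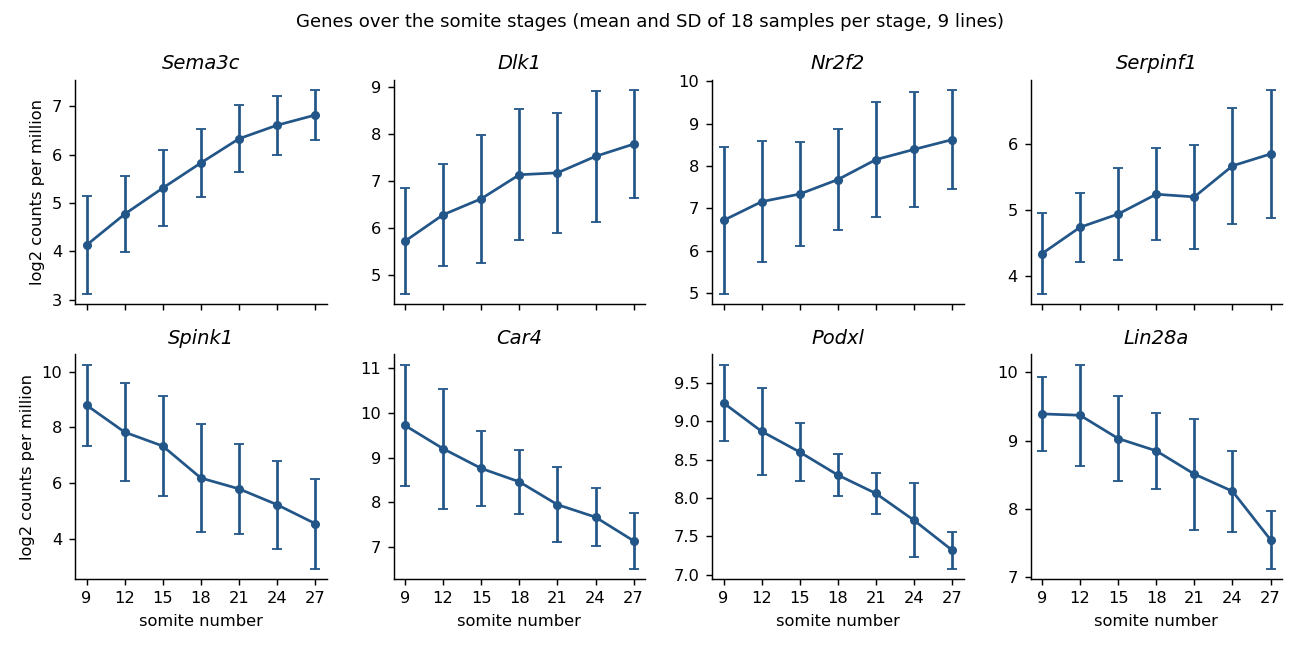
Log2 CPM of 8 genes (vertical) at 7 somite stages (horizontal), points and bars showing the mean and SD of 18 samples per stage. Sema3c goes from 4.13 to 6.82 and Podxl from 9.24 to 7.32.

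The second comparison asked whether lines differed in how genes moved with age. The tetraspanin gene Tspan7 (ENSMUSG00000058254.12, chromosome X, 10485158 to 10596605) ranked first (adjusted p 1.22e-22): over 18 somites it changed by -2.36 in Hhex and -2.20 in Nkx2_3, and by 0.94 in Mnx1GFP. Shh, a ligand gene of gut and notochord, changed by -3.67 in Pdx1 and by 2.75 in Pax9 (adjusted p 2.96e-17). Notochord-like cells, for which Shh is a marker, made 50.7 and 25% of the Pdx1 samples at 9 SS and 0% at 27 SS. On the same scale the sulfatase gene Sulf1 changed by -3.58 in Pdx1 and 1.81 in Pax9. Igf2 and H19, genes of 1 imprinted region, moved in both directions. Igf2 changed by 2.50 (Nepn) and 2.30 (Mnx1) but by -1.21 in Nkx2_3, and H19 by 2.54 in Nepn and -0.70 in Nkx2_3. Both rose in Hhex as well, and these single slopes were not tested. The cell cycle inhibitor gene Cdkn1a changed by 3.10 in Nkx2_3 and -1.04 in Wnt5b. The fibronectin gene Fn1 changed by -2.38 in Nkx2_3, Sec14l1 by 2.51 in Hhex and Dtx4, a Notch pathway gene, by 2.67 in Pdx1. In the F test of line by somite terms 7386 of 20824 genes passed, of which 5503 lay above 1 CPM on average. In simulated counts 151 unchanged genes passed, most of them nearer the floor, with 9 above 1 CPM. The count in the data was 1581 without replicate 1, 3408 without replicate 2 and 4730 without 12 SS.

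Each line was next set against the mean of the other 8 (14 samples against 112, 19988 genes), to ask what marks the cells it labels. These 9 comparisons share libraries and are not independent of each other. Across the 13 comparisons with fold changes, 209 of 442 list tests passed with the preset correlation and 69 with an estimated one. The Hhex line carried liver genes. Dlk1 was 7.11-fold higher than elsewhere (log2 2.83 ± 0.11, adjusted p 3.22e-44), the hepatoblast homeobox gene Prox1 7.58-fold (2.92 ± 0.12), and the plasma protein genes Afp, Apoe, Ttr and Rbp4 were higher by 3.55 ± 0.38, 2.92 ± 0.25, 2.67 ± 0.32 and 2.57 ± 0.31. Hhex itself was 10.8-fold higher (3.43 ± 0.22). The chemokine gene Cxcl12 (-3.16 ± 0.27) and the homeobox gene Msx1 (-2.71 ± 0.31) were lower. In all 3763 genes were higher and 3425 lower (3465 calls without replicate 1, 4773 without replicate 2). Of 25 hepatic genes 22 were higher and 0 lower (24 adjusted over the list alone; adjusted p 0.000412 with an estimated correlation), with Cebpa (3.44 ± 0.22) and Onecut1 (2.87 ± 0.21) among them. The biliary and ventral pancreas list was higher in 6 of 9 and lower in 3 (6 and 3 adjusted over the list alone; 0.000638), and the fetal maturation list in 7 of 12 and 3 (7 and 3 adjusted over the list alone; 0.000412), with the growth inhibitor gene Cdkn1c up by 2.0 ± 0.09. Position genes were lower: 14 of 16 anterior Hox genes (0.00203) and 21 of 22 posterior Hox genes (0.0109), counts that were 14 and 21 adjusted over the list alone. Signal response lists were lower as well, hedgehog in 11 of 14 (11 adjusted over the list alone; 0.00369), FGF response in 12 with 1 higher (12 and 1 adjusted over the list alone; 0.000638) and Notch in 12 of 17 with 1 higher (13 and 1 adjusted over the list alone; 0.0238). Their members include Gli3 (-1.27 ± 0.11), Spry4 (-2.65 ± 0.24) and Jag1 (-2.10 ± 0.33). Liver-like cells made 56.5% ± 11.8 of the line (SD, n = 14) against 1.06% elsewhere (permutation, adjusted p 0.000104), and extraembryonic endoderm-like cells 7.31% ± 6.29 against 0.61% (0.000104). Of these 7.31 percentage points, 6.27 were cluster 30, which has 4 of 6 markers, none in its top 10 genes, where Rbp4 leads. The other 1.04 were cluster 28, with all 6.

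Both Mnx1 lines and the Wnt5b line carried hindgut and tail genes. In Mnx1, the intestinal homeobox gene Cdx2 was higher by 2.36 ± 0.21, Wnt5b by 2.08 ± 0.14 and Fgf17, a tail-bud growth factor gene, by 2.94 ± 0.22. In Mnx1GFP the same genes were higher by 2.61 ± 0.20, 2.47 ± 0.13 and 3.73 ± 0.21, and in Wnt5b by 2.63 ± 0.20, 1.76 ± 0.14 and 3.52 ± 0.21. The driver Mnx1 was higher by 1.84 ± 0.20 in Mnx1 and 3.10 ± 0.19 in Mnx1GFP. Igf2 was lower in Mnx1 (-1.65 ± 0.18) and Mnx1GFP (-2.0 ± 0.19). Of 25 hindgut genes 24, 25 and 25 were higher in Mnx1, Mnx1GFP and Wnt5b and 0 lower (24, 25 and 25 adjusted over the list alone; adjusted p 0.000123, 0.000171 and 0.000142 with an estimated correlation). All 22 posterior Hox genes were higher in these 3 lines (22 adjusted over the list alone in each), among them Hoxa9 with 3.16 ± 0.26 in Mnx1 and 3.81 ± 0.25 in Wnt5b. The Wnt feedback list was higher in 10 of 16 genes in Mnx1 (11 adjusted over the list alone; 0.00824) and in 13 in Mnx1GFP (14 adjusted over the list alone; 0.000171), with 1 lower in each. The retinoic acid degrading enzyme gene Cyp26a1 rose with it (1.66 ± 0.22 and 2.65 ± 0.21). The counts were 2557 higher and 1749 lower in Mnx1 (1382 calls without replicate 1, 2371 without replicate 2) and 4083 and 4076 in Mnx1GFP (4354 without replicate 1). Hindgut-like cells made 40.2% ± 17.4 of Mnx1, 59.3% ± 18.8 of Mnx1GFP and 36.2% ± 12.4 of Wnt5b (n = 14 each, permutation, adjusted p 0.00321, 0.000104 and 0.0164). For Mnx1GFP that share was 29.4% at a clustering resolution of 2. Its 21 SS replicate 2 sample stood apart, with 4 of 140 hindgut-like cells and 134 unnamed, against 118 of 160 and 1 in replicate 1, and this pair had the lowest correlation across genes, 0.844. Most of these unnamed cells lay in cluster 29, which had 6 of 9 hindgut markers. That cluster stayed unnamed because 71.74% of its cells came from 1 sample, so the low share does not show that hindgut cells were missing.

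In the Wnt5b line, skin-side genes came with the hindgut genes. The homeobox genes Msx1 and Msx2, targets of BMP, were higher by 2.95 ± 0.19 and 2.44 ± 0.13, and the ligand gene Bmp4 by 1.76 ± 0.17. The nuclear receptor gene Nr2f2 (-2.73 ± 0.22), the gut hormone gene Pyy (-2.39 ± 0.58) and Sox2 (-1.37 ± 0.15) were lower. In all 4077 genes were higher and 3380 lower (4770 calls without replicate 1, 4121 without replicate 2). The BMP response list was higher in 8 of 14 (8 adjusted over the list alone; adjusted p 0.00466 with an estimated correlation). The p53 target list was higher in 10 of 16 and lower in 1 (11 and 2 adjusted over the list alone; 0.00272), with the death genes Pmaip1 (2.0 ± 0.22) and Perp (1.47 ± 0.14, or -0.04 with non-endodermal clusters left out) among them. The surface ectoderm list was higher in 11 of 14 and lower in 2 (11 and 2 adjusted over the list alone; 0.000239), with Tfap2a (3.12 ± 0.23) and the basal keratin gene Krt14 (4.99 ± 0.41). Of the esophagus and stomach list 9 of 12 genes were lower and 3 higher (9 and 3 adjusted over the list alone; 0.0347). Of 22 glycolysis genes 15 were higher and 1 lower (16 and 1 adjusted over the list alone; 0.321). Surface ectoderm-like cells made 18.1% ± 11.9 of the line against 3.61% elsewhere (n = 14, permutation, adjusted p 0.000104).

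The Nepn line carried midgut genes. Nepn was higher by 2.57 ± 0.33, the intestinal homeobox genes Isx and Cdx2 by 4.04 ± 0.24 and 2.46 ± 0.20, the fatty acid carrier gene Fabp1 by 3.19 ± 0.34 and Gata4 by 1.86 ± 0.21. The Notch ligand gene Jag1 (-3.36 ± 0.36), the retinoid carrier gene Crabp1 (-3.05 ± 0.34) and the FGF inhibitor gene Spry2 (-2.36 ± 0.38) were lower. In all 4172 genes were higher and 3958 lower (5144 calls without replicate 1, 4868 without replicate 2). The midgut list was higher in 15 of 20 and lower in 1 (15 and 1 adjusted over the list alone; adjusted p 0.0331 with an estimated correlation). The pharyngeal list was lower in 19 of 20 and higher in 1 (19 and 1 adjusted over the list alone; 0.003), with the thyroid genes Pax8 (-4.60 ± 0.49) and Foxe1 (-4.01 ± 0.49) among them. The Notch list was lower in 12 of 17 (13 adjusted over the list alone; 0.003), Hey1 by -1.85 ± 0.18. Midgut-like cells made 48.4% ± 31.2 of the line (0 to 85.3%) against 6.22% elsewhere (n = 14, permutation, adjusted p 0.000104). Cluster 6 made 24.1 of the 48.4 percentage points of midgut-like cells. It is a weakly marked cluster with 3 of 7 midgut markers and a mean log2 fold of -0.005 over all 7.

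The Nkx2_3, Pax9 and Sox2 lines carried pharyngeal genes. The cardiopharyngeal homeobox gene Nkx2-6 was higher by 2.55 ± 0.12, 2.43 ± 0.12 and 2.03 ± 0.13 in them, and the pharyngeal list was higher in 18, 18 and 17 of 20 genes and lower in 1, 0 and 0. These counts were the same adjusted over the list alone, with adjusted p 8.55e-07, 3.52e-11 and 4.16e-09 with an estimated correlation. The thyroid and lung bud list was higher in 6, 7 and 7 of 10 and lower in 0, 1 and 1 (the same adjusted over the list alone; 0.000341, 2.18e-06 and 0.000166). In Nkx2_3, Nkx2-3 was 36-fold higher (5.17 ± 0.28), the thyroid genes Pax8 and Foxe1 by 3.90 ± 0.25 and 3.54 ± 0.27 and the imprinted gene Mest by 2.08 ± 0.13, while Cdx2 (-5.58 ± 0.38) was lower. There 22 of 22 posterior Hox genes (22 adjusted over the list alone; 0.00158) and 16 of 22 pancreatic progenitor genes were lower, with 3 of the latter higher (16 and 3 adjusted over the list alone; 0.000341). Its surface ectoderm list was higher in 8 of 14 and lower in 1 (8 and 1 adjusted over the list alone; 0.0326), and surface ectoderm-like cells made 12.85% ± 7.95 of it against 4.27% elsewhere (n = 14, permutation, adjusted p 0.00697). In Pax9, Jag1 was 8.49-fold higher (3.09 ± 0.23), Pax9 6.00-fold (2.59 ± 0.20), the pharyngeal repressor gene Ripply3 by 2.36 ± 0.16 and Spry2 by 2.09 ± 0.27, while the keratin gene Krt8 was lower by -0.94 ± 0.09. In Sox2, Sox2 was higher by 1.40 ± 0.12 and the retinal dehydrogenase gene Aldh1a3 by 4.19 ± 0.28. The retinoic acid list was higher in 8 of 16 in both Pax9 and Sox2 (9 adjusted over the list alone in each; 0.000135 and 0.000481), and lower in 4 and 3. The counts were 3313 higher and 2801 lower in Nkx2_3 (3332 calls without replicate 1, 3738 without replicate 2), 3361 and 2951 in Pax9 (3541 and 2997) and 3145 and 2585 in Sox2 (3214 and 2822). Pharynx-like cells made 35.7% ± 14.9 of Nkx2_3, 55.8% ± 15.8 of Pax9 and 32.8% ± 10.8 of Sox2 (n = 14 each, permutation, adjusted p 0.00349, 0.000104 and 0.0111). Cluster 7 made 14.9 of the 32.8 percentage points in Sox2 and 9.8 of the 55.8 in Pax9. It is a weakly marked cluster with 4 of 9 pharynx markers, none in its top 10 genes, and a mean log2 fold of 0.11 over all 9. Thyroid-like cells made 15.1% ± 9.13 of Nkx2_3 against 1.02% elsewhere (0.000104).

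The Sox2 line also held ectoderm, neural and germ cell genes. Of the surface ectoderm list 11 of 14 were higher and 1 lower (12 and 1 adjusted over the list alone; adjusted p 0.000332 with an estimated correlation), with Tfap2a up by 3.87 ± 0.22. Of 13 neural genes 9 were higher and 1 lower (9 and 1 adjusted over the list alone; 0.00333), among them the neuronal regulator gene Neurog2 (4.62 ± 0.48). Of 12 germ cell genes 9 were higher and 0 lower (9 adjusted over the list alone; 0.000166), and germ cell-like cells made 1.74% ± 1.91 of the line against 0.03% elsewhere (n = 14, permutation, adjusted p 0.000104). The liver genes Ahsg and Alb were higher in it (7.0 ± 0.51 and 3.28 ± 0.49), and much of this lay in the replicate 1 samples of 24 and 27 SS, where Ahsg stood at 599.2 and 1199.3 CPM. Other plasma protein genes, Rbp4 (-3.06 ± 0.50), Afp (-2.42 ± 0.58) and Ttr (-2.04 ± 0.49), were lower.

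The Pdx1 line, a reporter without tamoxifen, carried pancreas and hormone cell genes. Pdx1 was 25-fold higher (log2 4.64 ± 0.30, adjusted p 1.35e-27), the progenitor gene Sox9 7.36-fold (2.88 ± 0.12) and the stomach hormone gene Ghrl 25.5-fold (4.68 ± 0.37). The retinol carrier gene Rbp4 was higher by 3.70 ± 0.30 and Gata4 by 2.81 ± 0.20, while Pax9 (-2.07 ± 0.29) and Ripply3 (-2.24 ± 0.24) were lower. In all 5274 genes were higher and 4954 lower, the most of the 9 lines. Of 22 pancreatic progenitor genes 20 were higher and 0 lower (20 adjusted over the list alone; adjusted p 0.000183 with an estimated correlation), of 49 endocrine genes 37 and 2 (38 and 3 adjusted over the list alone; 0.00957) and of 9 biliary genes 8 and 0 (8 adjusted over the list alone; 6.94e-06). The notochord list was higher in 10 of 12 and lower in 1 (10 and 1 adjusted over the list alone; 0.0174), with the BMP inhibitor gene Nog up by 2.79 ± 0.27. Of 22 dissociation stress genes 14 were higher and 1 lower (14 and 1 adjusted over the list alone; 0.216), with Fos at 2.26 ± 0.32 and Egr1 at 2.73 ± 0.35. Of 22 S phase genes 14 were lower and 1 higher (14 and 2 adjusted over the list alone; 0.216), with Pcna at -0.83 ± 0.06. Genes of cells outside the endoderm were higher too: 12 of 13 blood genes (12 adjusted over the list alone; 0.216), 7 of 10 cardiac genes (7 adjusted over the list alone; 0.301) and 11 of 20 mesenchyme genes with 2 lower (11 and 2 adjusted over the list alone; 0.292). Of 12 endothelium genes 11 were higher (12 adjusted over the list alone), but the list did not pass (adjusted p 0.259), and with a term for library differences 4 were higher. Biliary-like cells made 26.8% ± 14.9 of the line, pancreas-like cells 26.8% ± 19.3 and notochord-like cells 9.32% ± 13.78 (0 to 50.7%; n = 14, permutation, adjusted p 0.000104 each), but at a resolution of 0.5 no cluster took the biliary name. At resolution 1 that name rests on cluster 22, with 3 of 5 markers (Sox17, Hhex and Pdx1), none in its top 10 genes. Pancreas-like clusters 18, 21 and 32 had 7, 5 and 3 of 8 markers. Pdx1, the gene that the line reports, is a marker of both types and a member of the biliary and pancreatic lists. Part of these shares and list calls can thus be built in.

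**Figure D3:**
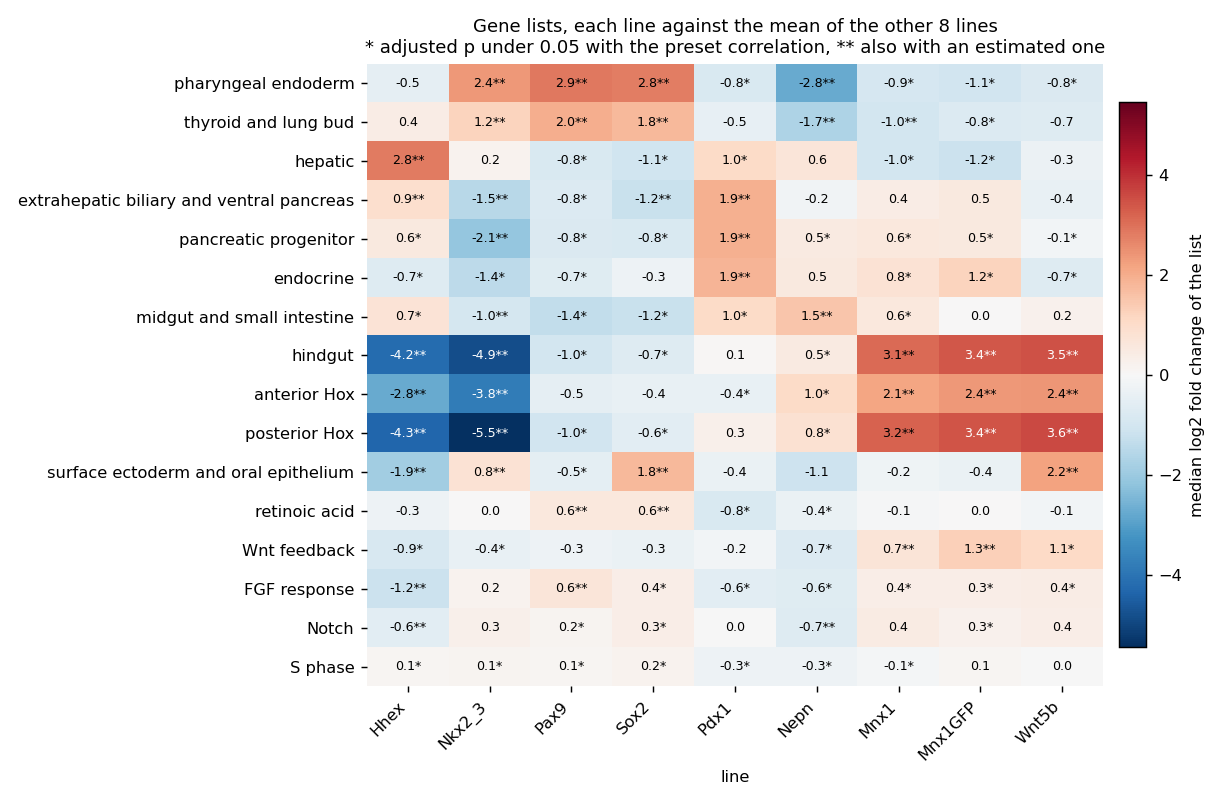
Median log2 fold change of 16 gene lists (vertical) in each of the 9 lines against the mean of the other 8 (horizontal); 1 star marks a call with the preset correlation and a pair of stars a call that also held with an estimated one. The hindgut list is higher in Mnx1, Mnx1GFP and Wnt5b and the pharyngeal list in Nkx2_3, Pax9 and Sox2.

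**Figure D4:**
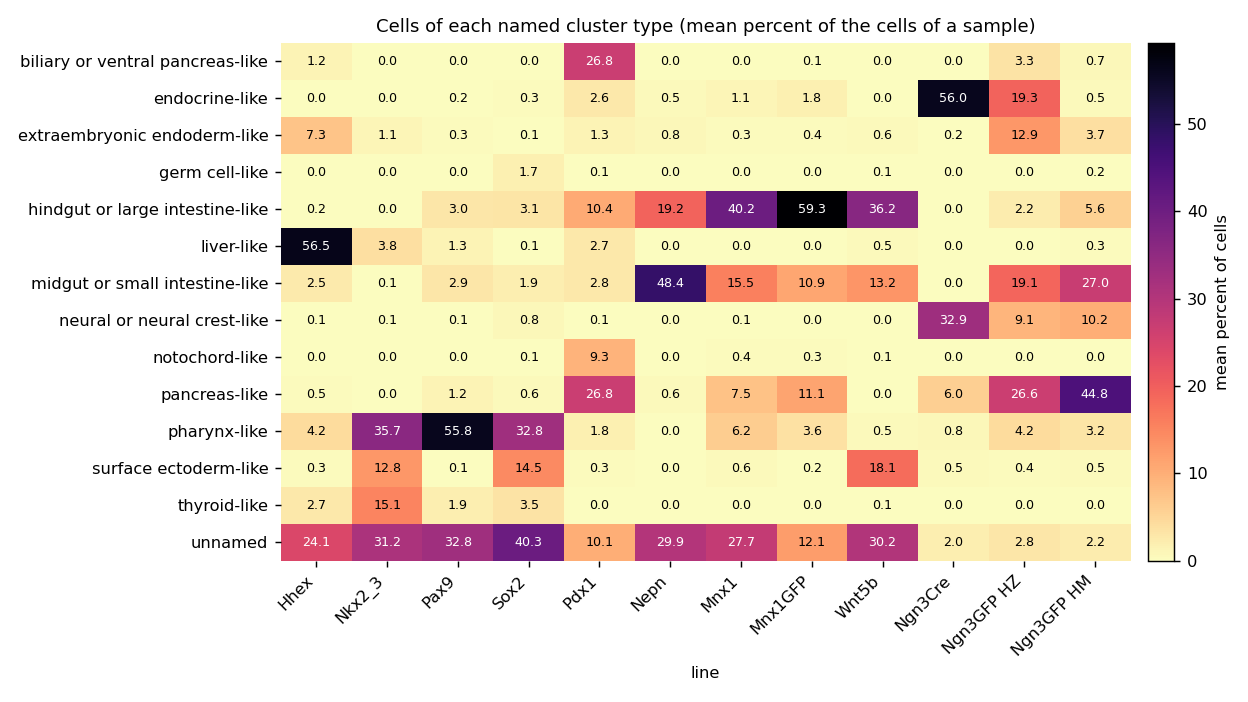
Mean percent of cells in clusters named after a cell type (vertical) in each line (horizontal), over 14 samples for the time-course lines. Liver-like cells make 56.5% of Hhex, hindgut-like cells 59.3% of Mnx1GFP and pharynx-like cells 55.8% of Pax9.

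Mnx1GFP and Mnx1 carry the same driver with different constructs, and were set against each other (14 samples each). Mnx1 was 2.17-fold higher in Mnx1GFP (log2 1.12 ± 0.31, adjusted p 0.00422), while Wnt5b did not pass (0.35 ± 0.22, adjusted p 0.269). The vesicle fusion gene Vamp3 (ENSMUSG00000028955.3, chromosome 4, 151047300 to 151057963) was 3.02-fold higher (7.72 ± 0.52 against 6.19 ± 0.49), the deacetylase gene Sirt6 3.32-fold and the cell cycle kinase gene Cdk6 3.64-fold. The histone genes Hist1h4d (-1.46 ± 0.28) and Hist1h1b (-1.38 ± 0.27), the glycosylation gene Ogt (-0.94 ± 0.11) and the hypoxia regulator gene Hif1a (-0.90 ± 0.15) were lower. In all 2080 genes were higher and 2459 lower, with 1005 calls without replicate 1, and 1878 among hindgut-like cells alone. These cells lie in different clusters: cluster 1 made 49.3% ± 21.0 of Mnx1GFP and 20.5% ± 24.8 of Mnx1, and cluster 2 made 1.1% ± 1.7 and 16.9% ± 17.0. Only 3 lists passed, and none held with an estimated correlation (adjusted p = 0.969 each) or with a term for library differences (0.299 each). Of 22 S phase genes 10 were higher (10 adjusted over the list alone), of 16 Wnt feedback genes 4 were higher and 1 lower (4 and 1), and of 25 hindgut genes 2 were higher (0 adjusted over the list alone).

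Replacement of Neurog3 (ENSMUSG00000044312.4, chromosome 10, 62133090 to 62134763), the switch gene of hormone cell formation, by GFP in both copies was examined by setting Ngn3GFP HM against HZ, 1 sample each at 5 stages. Neurog3 stood at 2.36 ± 0.92 log2 CPM in HM and 4.14 ± 1.31 in HZ (n = 5 each), a difference of -1.79 ± 0.40 that did not pass (adjusted p 0.586), so reads of the gene remain in HM. Only the imprinted gene Peg10 (ENSMUSG00000092035.8, chromosome 6, 4747306 to 4760517), a member of the endocrine list, passed. It was 5.52-fold lower in HM (log2 -2.46 ± 0.25, adjusted p 0.043), at 7.45 ± 0.86 against 9.91 ± 0.39, and lower at 5 of 5 stages. The count of 1 from edgeR compares with 1284 genes at an unadjusted p under 0.05 and 164 with DESeq2. It became 0 with RLE size factors and without the 21, 24 or 27 SS pair, and 9 without the 15 SS pair. Peg10 also lost its call with named non-endodermal cells left out and with a term for library differences. Of 49 endocrine genes 1 was lower and 0 higher (17 and 0 adjusted over the list alone), with a median of -1.75 and adjusted p 1.99e-26 with the preset but 0.947 with an estimated correlation. The G2 and M phase, cardiac and p53 target lists also passed only with the preset correlation, with 0 members called in each. With a term for library differences 11 lists passed with the preset correlation in place of 4. The hindgut (1.26e-08) and posterior Hox (7.15e-09) lists were then called upward, and the G2 and M phase list was not called (0.125). Endocrine-like cells were 0 of 31, 0 of 44, 1 of 100, 0 of 69 and 1 of 70 in HM from 15 to 27 SS, where the zeros allow shares of up to 9.68, 6.82 and 4.35%. In HZ they were 1 of 61, 0 of 76 (up to 3.95%), 9 of 22 (40.9%, exact 95% interval 20.7 to 63.7), 25 of 102 (24.5%, 16.5 to 34.0) and 30 of 102 (29.4%, 20.8 to 39.3). The mean share was 0.49% ± 0.68 in HM and 19.3% ± 17.9 in HZ (n = 5 each), lower in HM at 4 of 5 stages, with none in either at 18 SS. The exact permutation p was 0.125, the smallest possible with that tie.

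**Figure D5:**
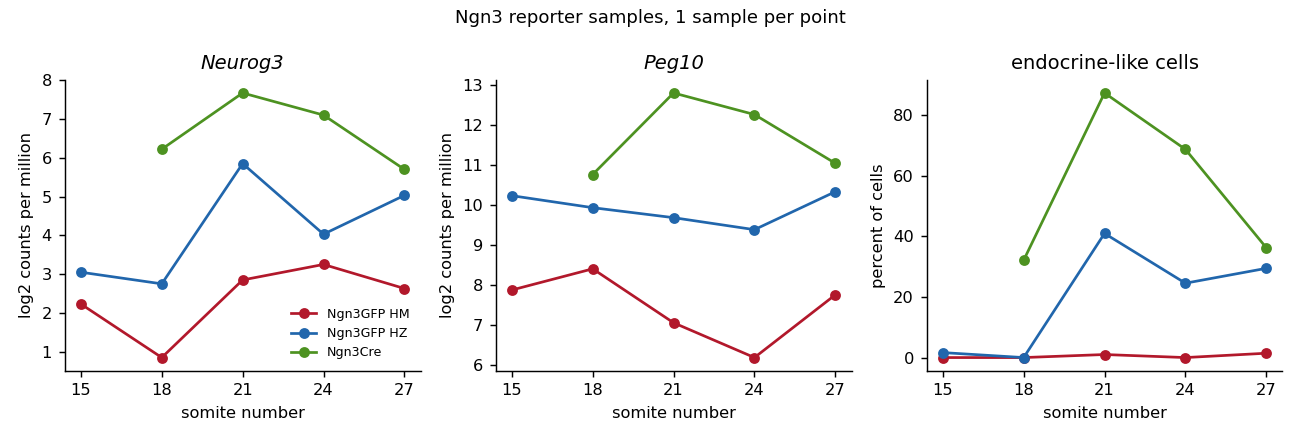
Log2 CPM of Neurog3 and Peg10 and percent of endocrine-like cells (vertical) by somite stage (horizontal) in Ngn3GFP HM, Ngn3GFP HZ and Ngn3Cre, 1 sample per point. Peg10 is lower in HM than in HZ at 5 of 5 stages.

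Ngn3Cre marks cells that once expressed Neurog3 and HZ cells that hold its reporter, and 4 samples of each were compared by stage. Neurog3 was 4.81-fold higher in Ngn3Cre (log2 2.27 ± 0.46, adjusted p 0.0384, 6.67 ± 0.88 against 4.41 ± 1.34). HZ has 1 copy of Neurog3 replaced by GFP, and its endocrine-like share was lower at each shared stage. What either adds to this difference was not tested. The transcriptional repressor gene Runx1t1 (ENSMUSG00000006586.15, chromosome 4, 13743436 to 13893649) was 6.98-fold higher, and the synaptic gene Snap25, the islet regulator genes Pax6 and Isl1 and the neuropeptide gene Gal by 3.17 ± 0.44, 2.87 ± 0.46, 2.67 ± 0.43 and 2.76 ± 0.41. The proteoglycan gene Sdc4 (ENSMUSG00000017009.3, chromosome 2, 164424247 to 164443887) was 8.52-fold lower (-3.09 ± 0.26), and the endoderm regulator genes Foxa1 and Gata4 and the glucose transporter gene Slc2a3 were lower by -2.88 ± 0.27, -2.59 ± 0.33 and -3.37 ± 0.38. In all 208 genes were higher and 314 lower of 16435, but leaving out the 24 SS pair left 6 calls and the 21 SS pair 305, and DESeq2 gave 2390. Of 49 endocrine genes 15 were higher and 0 lower (37 and 1 adjusted over the list alone; adjusted p = 0.288 with an estimated correlation), with the insulin gene Ins1 at 3.37 ± 0.37 and Neurod1 at 2.01 ± 0.31. Of 20 extraembryonic endoderm genes 10 were lower (13 adjusted over the list alone; 0.282), and of 19 midgut genes 6 (8 adjusted over the list alone; 0.211). None of the 20 lists called held with an estimated correlation. Endocrine-like cells were 51 of 159 (32.1%, exact 95% interval 24.9 to 39.9), 75 of 86 (87.2%, 78.3 to 93.4), 35 of 51 (68.6%, 54.1 to 80.9) and 21 of 58 (36.2%, 24.0 to 49.9) in Ngn3Cre from 18 to 27 SS. Midgut-like cells were 0 in each of these samples (up to 1.89, 3.49, 5.88 and 5.17%) and 14.5 to 26.5% of the 4 HZ samples. Extraembryonic endoderm-like cells were 1 of 159 in Ngn3Cre and 20 of 76 (26.3%, 16.9 to 37.7) in HZ at 18 SS, and at 21, 24 and 27 SS 0 of 86, 0 of 51 and 0 of 58 (up to 3.49, 5.88 and 5.17%) against 0 of 22 (up to 13.6%), 2 of 102 and 0 of 102 (up to 2.94%). Neural-like cells made 32.9% ± 28 of the Ngn3Cre samples (n = 4, 5.8 to 58.6%) and 9.09% ± 4.3 of HZ (n = 5, 4.9 to 14.7%). With them left out 1325 genes were called, of which 476 were among the 522.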

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

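Among the tests below, the library axis, the removal of named clusters, the hindgut-like cells alone, the counts from 1 CPM and the test and removal of the Wnt5b 9 SS replicate 2 sample were chosen after the data were seen. In 117 series of 4 or 5 Ngn3 samples, 6 had a sample far from the others, where chance gives about 1 in 20. The gap to the nearest sample, as a share of the range, was 0.728 for Pax6 in HM, where 18 SS was lowest (-2.80 against 0.90 for the next). It was 0.778 for Aurkb in HZ, where 27 SS was lowest (5.03 against 5.87). In Ngn3Cre the 21 SS sample was lowest for Aurkb (0.902), Dhrs3 (0.972) and Rarb (0.884), and the 27 SS sample for Sdc4 (0.917, 5.66 against 6.76). Of the 6, 3 lie in 1 sample, and no cause was tested.

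The change with somite number differed between the 9 lines, by the F test of line by somite terms, for Tspan7 (adjusted p 1.22e-22), Igf2 (7.07e-21), Fn1 (7.4e-19), Sec14l1 (1.43e-18) and H19 (4.13e-18). It also differed for Shh (2.96e-17), Dtx4 (4.32e-17), Cdkn1a (2.99e-16), Sulf1 (6.36e-16) and Fermt1 (4.11e-14). Igf2 and H19, neighbours under joint imprinted control, both rose in Hhex, Mnx1, Mnx1GFP, Nepn and Wnt5b and fell in Nkx2_3, Pax9 and Sox2, while in Pdx1 they changed by 0.16 and -0.17. Neither these single slopes nor their likeness was tested. Shh and Sulf1 fell in Pdx1 by 3.67 and 3.58 and rose in Pax9 and Nkx2_3. Notochord-like cells, for which Shh is a marker, were 36 of 71 in 1 Pdx1 sample at 9 SS and 0 at 27 SS. Without named non-endodermal cells Shh was still called, but 36 cells of an unnamed cluster with the same markers stayed in, so a part for them is open.

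Regrouping the samples at random tested whether chance could give the counts of called genes. Chance can be excluded for somite number (8784 genes against at most 7 in the other splits of 25, where 1 split, the real one, gave as many). For slope differences, 7386 genes compare with at most 816 in the other splits of 21, which had a median of 425.5 calls. These splits moved somite numbers within each line, which also removes the change that the lines share. They therefore cannot decide whether chance gave the differences between slopes. On simulated counts the slope difference test called 151 unchanged genes, of which 9 had at least 1 CPM, so it calls genes of low expression too readily. Chance can also be excluded for each line. The highest other counts were 960 for Hhex (7188), 104 for Mnx1 (4306), 117 for Mnx1GFP (8159), 391 for Nepn (8130), 161 for Nkx2_3 (6114), 59 for Pax9 (6312), 805 for Pdx1 (10228), 247 for Sox2 (5730) and 104 for Wnt5b (7457). It can be excluded for the Mnx1 pair (4539 against at most 1005 in the other splits of 25). For Ngn3Cre against HZ, 522 genes compare with at most 1 in the other splits of 32, where 3 more could not be fitted. Those splits moved samples across stages, although the comparison pairs samples by stage, so they cannot decide whether chance gave the count. Chance cannot be excluded for HM against HZ, where 9 of 100 such splits, the real one included, gave as many as 1 gene and the highest other gave 8.

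The Mnx1GFP and Mnx1 lines differed in 4539 genes although both carry a Mnx1 driver. Reads per cell are argued against, since 4395 genes were called with cells thinned to 1 depth. A difference between libraries stays open: the fold change followed the loading of the main axis of replicate differences in the 7 other lines, with Pearson r = 0.532 across 9404 genes, which are not independent replicates. A term for that axis left 4638 calls, 3194 of them among the 4539. Mnx1GFP samples scored 1.00 ± 1.04 on it and Mnx1 samples 0.02 ± 1.19 (SD, n = 14 each). The 2 Mnx1 samples of a stage lay far apart at 9 SS (-1.39 and 1.08), 12 SS (-0.53 and 1.65) and 15 SS (-1 and 1.79). They did so too at 21 SS (1.39 and -1.02) and 24 SS (1.34 and -1.11), but not at 18 and 27 SS. Some Mnx1 samples thus scored above the Mnx1GFP mean. Different cell type shares cannot be told apart from the line, because the 1878 calls among hindgut-like cells alone could reflect fewer cells. These cells also lie in different clusters, with 49.3% ± 21.0 of Mnx1GFP and 20.5% ± 24.8 of Mnx1 in cluster 1 and 1.1% ± 1.7 and 16.9% ± 17.0 in cluster 2. Nepn and Wnt5b, with low mean scores on the library axis (-0.97 and -0.72, against 1.00 in Mnx1GFP), hold mostly cluster 2 (19.2 and 32.6%). The split of clusters therefore does not by itself part cell kinds from libraries. Its relation to the axis was not tested over all lines. An effect of the constructs is a further open explanation and was not tested.

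The Pdx1 line had the most calls of the 9 lines, 10228. With the axis term 9095 were called, without named non-endodermal clusters 10023, and with thinned cells 9172, so none of these alone accounts for the count. It is the line with a direct reporter and without tamoxifen. That design and a difference of its cells cannot be told apart here.

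In the Wnt5b 9 SS replicate 2 sample, 160 of 160 cells held reads of Ctrb1, an enzyme gene of the mature exocrine pancreas (exact 95% interval 97.7 to 100%). There the gene stood at 80.1 CPM, against at most 0.7 in any other sample, and Ins2 stood at 368.4 CPM. The next highest Ins2 was 95.5 CPM, in Wnt5b 27 SS replicate 2, against a median of 1.93 in other samples. No Wnt5b cell was endocrine-like, so Ins2 reads without such cells were not confined to 1 sample. Of its cells with a Ctrb1 read, 11.88% (19 cells) also held a read of Pdx1 or Ptf1a. This argues against most of the 160 cells being pancreatic. Because every cell held Ctrb1, the value cannot decide whether a smaller number of pancreatic cells lay within the 9 SS sample. RNA carried in from other cells or another library could give Ctrb1 reads in all cells. Leaving the sample out changed the Wnt5b count from 7457 to 6935.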

How the results depend on the processing

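The terms for library differences, the removal of named clusters, the hindgut-like cells, the counts from 1 CPM and the removal of samples with carried-over transcripts were chosen after the data were seen. For somite number, slope differences and the 9 lines, counts stayed within 1.5 times under DESeq2, RLE size factors, no filter, thinned cells, the gene minimum, the library axis and all added removals. Of 298 single gene results followed, 5835 of 5943 values kept direction and side of the threshold, 91 lost the call and 16 gained it. Only Perp in Wnt5b changed sign, to -0.04 without named non-endodermal cells, so its higher level in that line depended on those cells. Perp is also a member of the surface ectoderm list. Which of the removed clusters mattered was not tested. With an estimated correlation 69 of 209 list calls held, as that test allows for genes moving together.

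Leaving out replicates or stages, which leaves fewer samples, gave 4793 to 9013 genes for somite number, 1581 to 7704 for slope differences, 3465 to 7150 for Hhex, 1382 to 4411 for Mnx1, 4354 to 8086 for Mnx1GFP and 4868 to 8134 for Nepn. The ranges were 3332 to 6219 for Nkx2_3, 2997 to 6276 for Pax9, 2822 to 5734 for Sox2, 4121 to 6935 for Wnt5b and 1005 to 4505 for the Mnx1 pair. HM against HZ ranged from 0 to 9 and Ngn3Cre against HZ from 6 to 520. With a replicate block the counts were 8850 for somite number, 6683 for slopes, 7199, 4304, 8172, 8202, 6204, 6249, 10183, 5821 and 7540 for the lines in the order Hhex, Mnx1, Mnx1GFP, Nepn, Nkx2_3, Pax9, Pdx1, Sox2 and Wnt5b, and 4522 for the Mnx1 pair.

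For HM against HZ, 1 gene became 0 with RLE, 3 without a filter, 164 with DESeq2, 11 with thinned cells, 0 with the axis, 2 without neural-like cells, 13 without non-endodermal cells and 1389 with all 140 samples in 1 fit. Peg10, the gene called in the main fit, lost its call without non-endodermal cells and is not among those 13. For Ngn3Cre against HZ, 522 became 1086 without a filter, 2390 with DESeq2, 1325 without neural-like cells, 2027 without non-endodermal cells and 4744 with all 140 samples. The pooled fit takes its spread from replicates of other lines; the other causes were not tested. The Mnx1 pair gave 1878 among hindgut-like cells, which are fewer. An alternative with only cells of deposited endocrine or pancreatic types was not run, since the cell table names no types. The Ngn3 lines had the smallest sample, of 22 cells.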

Other observations

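Apart from the list tests, the tests in this part were chosen only after the results were seen. Several lists outside the main pattern of a line held with an estimated correlation. In Nkx2_3 the fetal maturation list was higher in 8 of 12 genes (adjusted p 0.000894), with Igf2 up by 1.41 ± 0.14, and it was lower in Mnx1 (6 of 12, 0.00865) and Mnx1GFP (9 of 12, 0.00637). The FGF response list was higher in 9 of 14 genes in Pax9 (0.0363), with Spry1 up by 1.15 ± 0.10 and Spry2 by 2.09 ± 0.27. In Sox2 the early embryonic list was higher in 10 of 18 (0.00871), a list that shares Pou5f1 and Nanog with the germ cell list. The p53 target list was lower in Hhex (9 of 16, 0.0432) and Nkx2_3 (7 of 16, 0.0452) and higher in Mnx1 (6 of 16, 0.0441).

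Neural-like cells, 246 in all with 88 in the Ngn3Cre 18 SS sample and 34 in that of 27 SS, held 2020.2 CPM of Tubb3. Endocrine-like cells held 345.4 CPM. The neural-like cells held little Foxa2 (2.0 against 149.3 CPM) and less Epcam (122.9 against 300.4 CPM), the gene of the sorted surface protein.

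The replicate 1 samples of Sox2 at 24 and 27 SS held 574.5 and 411.7 CPM of Alb, 102.3 and 41.5 CPM of Cyp2e1, an enzyme gene of the mature liver, and 54.2 and 78.2 CPM of the macrophage gene Lyz2. In other samples the median of Lyz2 was 0 CPM. In the Mnx1GFP 21 SS replicate 2 sample 139 of 140 cells held reads of the predicted gene Gm10800 (exact 95% interval 96.1 to 100%), at 1727.7 CPM against at most 270.4 in any other sample. The Pdx1 15 SS replicate 2 sample held 4029.9 CPM of the embryonic globin gene Hbb-y, and 67.6% of its 111 cells had a read of it (exact 95% interval 58.0 to 76.2).

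Differences between the 2 samples of a group had a main axis that took 24.9% of their squared size over 9404 genes, against 7.2% for the second. On it 75 of 77 ribosomal protein genes loaded negatively. The axis score of the 63 groups went with the difference in detected genes per cell (Pearson r -0.427, permutation p 0.00062, adjusted 0.00124; Spearman rho -0.396, permutation p 0.00157, adjusted 0.00314; r -0.394 without the 2 farthest groups). It did not go detectably with reads per cell (r -0.161, permutation p 0.206; rho -0.157, permutation p 0.217; r -0.141 without the 2 farthest). These were the only 2 relations of the score differences computed. Across 9146 genes, which are not independent replicates, the axis loading had a Spearman correlation of -0.009 with transcript length and -0.142 with transcript GC. Of the score variance over the time-course samples, 50% lay between lines and 29.1% between samples of a group. By reads of Xist and of Y genes, 129 of 140 samples were mixed or unclear, in 8 at least 90% of cells had a Y read and at most 10% an Xist read, and in 3 the reverse held. In some samples most single cells of at least 100000 reads held both kinds. They were 129 of 153 in Hhex 12 SS replicate 2 and 153 of 182 in Nepn 24 SS replicate 1, against 7 of 254 in Hhex 24 SS replicate 1. A mixed sample therefore need not be a pool of both sexes, and the cause was not tested.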
